A study of Mus musculus with 46 samples.

How the data were processed

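The libraries came from single neurons of mice aged postnatal day 21 to 30, whose cytosol was drawn into a patch pipette. Per the labels, each cell was anatomically an oriens-lacunosum moleculare (OLM) interneuron, had passed quality control, and came from an Htr3a-Cre or an Sst-Cre driver line, with 23 cells of each. Each deposited sample is 1 cell and the labels name no animal. Each line was therefore treated as 1 sample, no test between the lines was made, and no p-value is given.

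The deposited count tables hold raw read counts per gene, by symbol for 22800 genes and by Ensembl identifier for 22880. Trimmomatic, STAR, featureCounts and the genome build GRCm38 are named per the submitters' processing notes. Their versions, the annotation and the strand setting are not given in the sources used here, so reads of overlapping genes cannot be told apart. The deposited normalized table is a signal on a linear scale: 100% of its non-zero values lay within 0.1% of the count divided by 1 factor per cell, and these factors ranged from 0.144 to 2.09. How the authors chose the factors is not given in the sources used here. No molecular identifiers are named, so copies of 1 molecule could be counted more than once, and the intervals below cover counting error only.

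Of the Ensembl identifiers, 22570 matched the GENCODE M21 annotation of GRCm38, as did 21906 of the symbols. Of 21698 symbols compared between the count tables, 21665 had identical counts. The driver line written in the table was the labelled line for 46 of 46 cells. Of 1035 pairs of libraries, 0 were identical, and their correlations across genes ranged from 0.224 to 0.655, so each library was counted once. The table by symbol was the main input.

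Counts were scaled to a total of 1000000 per cell (CPM) and expressed as log2(CPM + 1). The line difference of a gene is the mean over Sst-line cells minus the mean over Htr3a-line cells, so a negative value means lower in the Sst line. It weighs each cell equally, and for genes missed in some cells it can lie above or below the log2 ratio of CPM summed over a line, which was taken with 1 added to each sum. SDs are between cells. Shares of cells with at least 1 read carry exact Clopper-Pearson 95% intervals, and the CPM of counts summed over a line carries an exact Poisson 95% interval. A share of 0 allows up to 3 cells of the total, which limits cells with a read and not cells expressing the gene.

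The 28 gene lists, the named-gene rule and the alternatives were set before the data were examined. A list is described by the median line difference of its members with a mean of at least 0.5, and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is not a test. Similarity of the lines is the Pearson correlation across genes of mean profiles of 11 random cells per line, beside that of 2 disjoint sets of 11 cells within a line, over 100 draws.

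The rule for named genes takes every measured member of the OLM identity, GABAergic, medial ganglionic eminence and caudal ganglionic eminence lists. It adds the 12 lowest and 12 highest line differences among genes with reads in at least 12 cells whose summed CPM and share of cells do not go the other way. Sex-linked genes, predicted gene names and pseudogenes are left out there, which removed 0 names. It adds, from every other list, up to 3 members with the largest size of difference among those with reads in at least 12 cells. Some genes that the rule takes are not reported here. Other genes are said to have been chosen after their values were seen. For each gene, the share of its 31-base words that also occur in transcripts of other genes of GENCODE M21 measured how far reads could be split between similar genes. Of the 5 sex-linked genes listed, 4 were analysed.

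The calculations were tested on simulated counts for the 22800 genes, made by shuffling each gene's values over all cells at the real library sizes. Of 100 genes then raised 4-fold in the Sst line, 93% had a positive difference, with a median recovered shift of 1.49 for a true log2 of 2. Of 100 genes lowered to 0.25-fold, 98% had a negative difference, with a median of -1.49. The changed genes were drawn from those with a mean log2(CPM + 1) of at least 3, and values of 0 stayed 0. These 2 shares therefore do not cover sparser genes or differences in the number of cells with reads. A list of 12 raised genes fell at percentile 100 and a list of 12 lowered genes at 0, while 5.5% of 200 lists of unchanged genes lay outside the middle 95%. Each gene was shuffled on its own, so this share holds for genes that vary independently. It does not extend to lists whose members vary together over cells, such as the microglial genes below.

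The alternatives were 5 reads or 10 CPM as the detection minimum, a pseudocount of 10, size factors from edgeR 4.0.16 (TMMwsp) and DESeq2 1.42.0 (poscounts), the deposited normalized table, summed counts, medians, other expression minimums, 10 bins, rank correlation, the table by Ensembl identifier, each cell left out in turn, and thinning of each cell to 5000000 reads. Leaving out each cell in turn from the summed CPM was added after the values were seen. Thinning left out 1 Htr3a-line cell and 0 Sst-line cells. Both packages were used for size factors alone, and no count model was fitted. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.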

Results

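OLM interneurons are dendrite-targeting cells of the hippocampal stratum oriens. Single OLM cells were profiled by RNA sequencing from a mouse line driven by Htr3a, a serotonin receptor gene that marks interneurons of the caudal ganglionic eminence (CGE), and from a line driven by Sst, the somatostatin gene, which marks interneurons of the medial ganglionic eminence (MGE). The comparison asks whether OLM cells labelled in the 2 lines carry the same transcripts. The 23 Htr3a-line cells had a median of 15336981 assigned reads (range 3391829 to 26136222), and the 23 Sst-line cells had 16726879 (5639490 to 31386369). A median of 8169 genes had a read in Htr3a-line cells (3350 to 12693) and 6569 in Sst-line cells (3225 to 8774). After thinning to 5000000 reads the medians were 7901.5 genes in 22 cells and 6477 in 23 cells. Over the 11196 genes with a mean log2(CPM + 1) of at least 0.5, the median line difference was -0.22, and it lay between -0.45 and -0.06 with a pseudocount of 10, under other scalings and after thinning. Over the 160 genes with a mean above 9 it was 0.29, and between 0.14 and 0.31 in these, so single differences are to be read against the shift at their level.

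**Figure D1:**
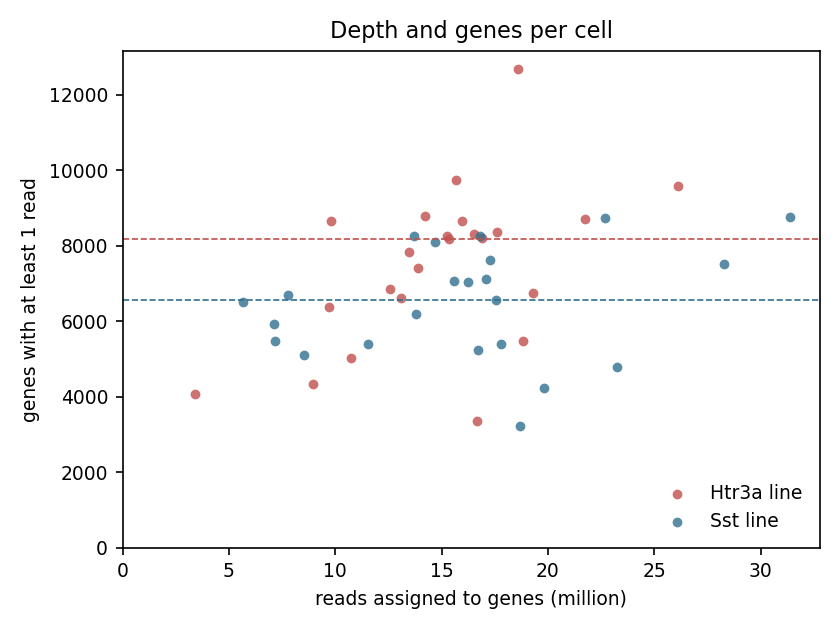
Genes with at least 1 read (vertical axis) against assigned reads in units of 1000000 (horizontal axis) for each cell, colored by driver line, with dashed lines at the medians of 8169 genes in the Htr3a line and 6569 in the Sst line. The ranges of depth overlap, and the highest number of genes, 12693, was in an Htr3a-line cell.

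Cells of both lines carried OLM transcripts, with Sst the most abundant of the OLM genes. Sst (chromosome 16, 23889573 to 23890958, GRCm38, protein-coding) was read in 23 of 23 cells of each line (100%, 95% interval 85.2 to 100). Its mean log2(CPM + 1) was 12.81 ± 1.5 (SD, 23 cells) in the Sst line and 14.20 ± 1.32 (23 cells) in the Htr3a line, a difference of -1.39 that is close to the SDs between cells. Summed over cells, Sst took 12592 CPM (12581 to 12604) and 27283 CPM (27266 to 27301). Crhbp, the corticotropin-releasing hormone binding protein, was read in 23 cells of each line and was higher in the Sst line (9.96 ± 1.17 against 8.63 ± 2.54, difference 1.33). The Crhbp difference was 0.39 by summed CPM, as a log2 ratio (1332 against 1013), and 0.69 by medians. It reached 10 CPM in 21 Htr3a-line and 23 Sst-line cells. Htr3a line replicates 4 and 20 stood apart, with 22 and 18 Crhbp reads (2.45 and 5.31 CPM).

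Chrna2, a nicotinic receptor subunit that marks OLM cells, was read in 6 of 23 Sst-line cells (26.1%, 10.2 to 48.4) and 10 of 23 Htr3a-line cells (43.5%, 23.2 to 65.5), intervals that overlap. Elfn1, a synaptic adhesion protein, was read in 15 and 18 cells (difference -1.08). Pnoc was read in 13 and 14 cells with a difference of -0.52, which was -0.21 without Htr3a line replicate 20, -0.33 without Htr3a line replicate 5, -0.35 without Htr3a line replicate 9 and -0.79 without Sst line replicate 1, and its summed CPM was 107 in the Sst line, 63.8 without Sst line replicate 1, and 70.7 in the Htr3a line. Reln (-0.07) and Npy (0.03) changed sign with the scaling. Of the 8 OLM genes, 6 were lower and 2 higher in the Sst line, with a median of -0.69 at percentile 0.44 of matched random lists. The percentile was 3.69 with a pseudocount of 10, 2.92 after thinning, 3.49 without Htr3a line replicate 20 and 2.71 without Htr3a line replicate 9.

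GABAergic genes were read in both lines. Gad1 and Gad2, which encode the enzymes that make GABA, were read in 23 of 23 cells of each line, with median CPM of 1069 and 738 in the Sst line and 1063 and 832 in the Htr3a line. The mean difference of Gad1 was 0.90, but 0.19 by summed CPM and 0.51 without Htr3a line replicate 4, which held 4 Gad1 reads. Htr3a line replicate 20 held 24 Gad1 reads. Gad2 was at 0.23, with the other sign under another scaling. Slc32a1, the vesicular GABA transporter, was read in 22 cells of each line (0.39). Of the interneuron transcription factors, Dlx1 was read in 20 cells of each line (-0.17), Dlx2 in 14 Sst-line and 17 Htr3a-line cells (-0.53, -0.33 without Htr3a line replicate 8, and by summed CPM -0.13, from -0.59 to 0.08 with each cell left out), Dlx5 in 14 and 15 (-0.17) and Dlx6 in 10 and 8 (0.01, of either sign by scaling). The list had 5 genes higher and 4 lower, and its median of 0.01 (percentile 61.8) changed sign under another scaling.

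Of the MGE lineage factors, Lhx6, Satb1 and Maf were read in most cells of both lines. Lhx6, which specifies MGE interneurons, had reads in 18 of 23 Sst-line cells (78.3%, 56.3 to 92.5) and 21 of 23 Htr3a-line cells (91.3%, 72.0 to 98.9), and Sox6 in 12 and 19. Their mean differences were -1.38 and -0.64. The summed CPM of Lhx6 was 142 and 138, in an order that changed with some single cells left out (112 in the Sst line without replicate 1), and that of Sox6 went the other way, at 31.2 and 20.8. Satb1 was read in 23 cells of each line (0.01) and Maf in 22 and 23 (-0.24), both of either sign by scaling. Nkx2-1 (-0.05) and Lhx8 (-0.15) each had reads in 1 Htr3a-line cell and 0 Sst-line cells. The 5 genes above the expression minimum, 4 lower and 1 higher in the Sst line, had a median of -0.64 (percentile 10.3).

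Most CGE lineage genes were sparse in both lines. Htr3a (chromosome 9, 48899213 to 48911099, protein-coding) had reads in 5 of 23 Htr3a-line cells (21.7%, 7.46 to 43.7) and 2 of 23 Sst-line cells (8.70%, 1.07 to 28.0), intervals that overlap. It reached 10 CPM in 3 Htr3a-line and 2 Sst-line cells. Its summed CPM was 28.2 in the Htr3a line, 7.07 without Htr3a line replicate 2, and 12.5 in the Sst line, 1.44 without Sst line replicate 9. Nr2f2, a nuclear receptor enriched in CGE interneurons, was read in 16 Htr3a-line and 11 Sst-line cells (-1.24), with summed CPM of 65.4, or 42.1 without Htr3a line replicate 6, and 17.3, or 9.45 without Sst line replicate 3. Npas1 was read in 20 and 18 cells (-0.07, of either sign by scaling). Adarb2 was read in 4 and 1 cells (-0.29, and by summed CPM -2.42, from -4.13 to 1.51 with each cell left out), Cxcl14 in 2 and 1 (0.01, of either sign by scaling), and Prox1 (-0.25) and Sp8 (-0.10) in 1 Htr3a-line cell and 0 Sst-line cells. The Prox1 and Sp8 reads, like those of Nkx2-1, all came from Htr3a line replicate 10, the cell with the most genes read (12693). Without Htr3a line replicate 4, which held 4 Gad1 reads, the summed CPM of Adarb2 in that line fell from 16.5 to 0.146. The 3 genes above the expression minimum had a median of -0.36 (percentile 27.3).

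**Figure D2:**
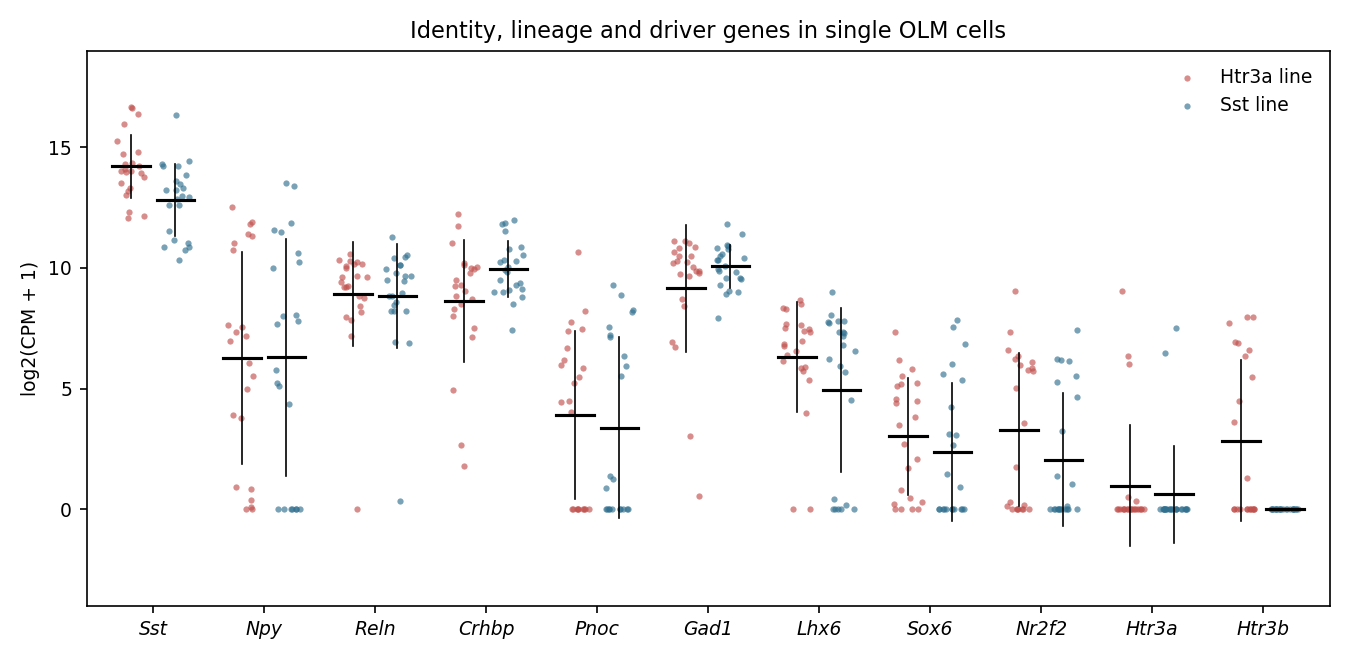
Level of 11 genes as log2(CPM + 1) (vertical axis) in each cell, by gene (horizontal axis) and driver line, with thick bars for the means and thin lines for 1 SD to either side. Sst is highest in both lines (means 14.20 in the Htr3a line and 12.81 in the Sst line), and Htr3b, chosen after its values were seen, has reads in 11 Htr3a-line cells and 0 Sst-line cells.

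Serotonin receptor genes were read in a minority of cells. Htr2a was read in 10 Htr3a-line and 11 Sst-line cells (difference 0.07, of either sign by scaling), and Htr1a in 8 and 6 (0.22). Htr3b, whose product assembles with that of Htr3a, and Htr1f were chosen after their values were seen. Htr3b (chromosome 9, 48935008 to 48964990, protein-coding) had reads in 11 of 23 Htr3a-line cells (47.8%, 26.8 to 69.4) and at least 10 CPM in 10 of them. It had reads in 0 of 23 Sst-line cells, which allows a share of up to 13%. Htr1f had reads in 8 of 23 Htr3a-line cells (34.8%, 16.4 to 57.3) and 0 Sst-line cells. The 6 receptor genes above the expression minimum had a median of -0.14 (percentile 62.8), 3 higher and 3 lower.

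**Figure D3:**
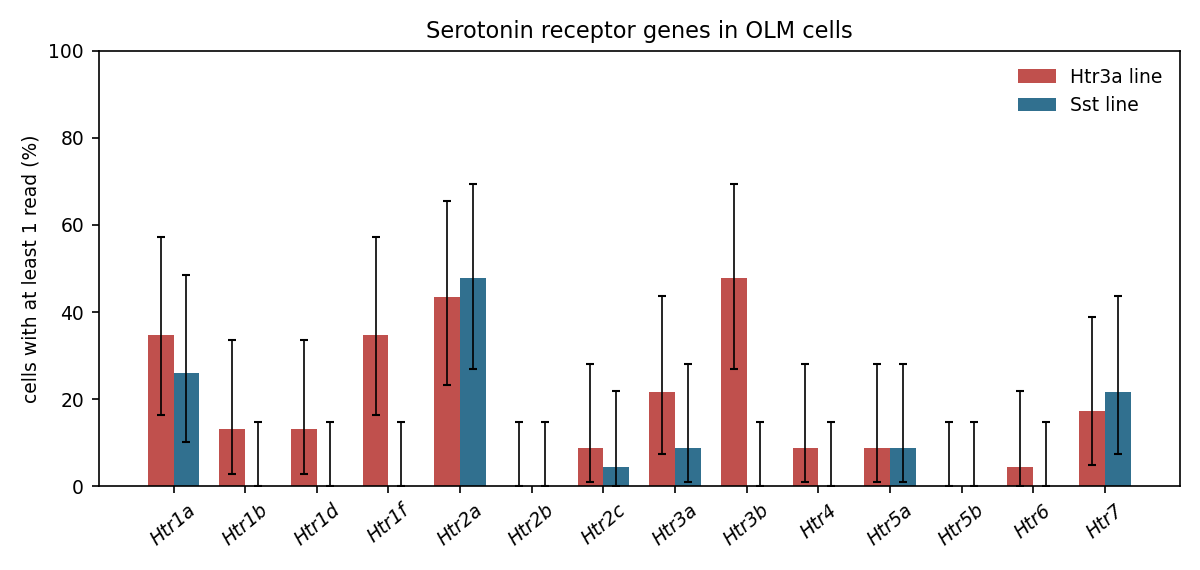
Percentage of cells with at least 1 read (vertical axis) of each serotonin receptor gene (horizontal axis), by driver line with 23 cells each, with exact 95% intervals for counting error as error bars. Htr3b stands at 47.8% in the Htr3a line and 0 in the Sst line, and Htr2a at 43.5% and 47.8%.

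The 12 lowest line differences ranged from -3.58 to -2.75. Camta2, a transcription activator, was read in 13 Sst-line and 21 Htr3a-line cells (2.43 ± 3.18 against 6.01 ± 2.84, 23 cells each). Ndn, an imprinted neuronal gene (chromosome 7, 62346569 to 62350262), was read in 18 and 23 cells (6.41 ± 3.73 against 9.80 ± 0.82, difference -3.39). Bcl2l1, which encodes an inhibitor of apoptosis, was read in 10 and 20 cells (-3.22), Pcsk1, a prohormone convertase, in 5 and 16 (-2.90), and Rgs4, a regulator of G-protein signalling, in 10 and 19 (-2.85). The others were AU040320 (-3.31), Tubgcp2 (-3.16), Fam73a (-3.06), Tmem229b (-2.97), Tbc1d19 (-2.82), Rad51d (-2.76) and Taf6 (-2.75). By summed CPM the 12 ranged from -3.28 (Rad51d) to -0.32 (Tbc1d19) with a median of -1.69, and 9 were smaller by over 1.5 times, among them Camta2 (-1.86), Ndn (-1.57) and Tubgcp2 (-0.91). Leaving out 1 cell moved a summed CPM by over 1.5 times in 7 of the 12.

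The 12 highest line differences ranged from 2.12 to 2.54. Ide, the insulin-degrading enzyme, was read in 17 Sst-line and 10 Htr3a-line cells (4.49 ± 3.28 against 1.94 ± 2.57, 23 cells each). Ythdf3, a reader of methylated RNA, was read in 18 and 11 cells (2.48), and Col25a1, a membrane collagen, in 19 and 14 (2.24). The others were Trappc9 (2.40), Ccrn4l (2.39), Tmem60 (2.30), Mzt1 (2.19), Snapc1 (2.19), Nlk (2.16), Grwd1 (2.14), Ergic2 (2.13) and Leng8 (2.12). By summed CPM the 12 ranged from 0.93 (Tmem60) to 2.53 (Nlk) with a median of 1.25, and 7 were smaller by over 1.5 times, among them Trappc9 (0.99) and Col25a1 (1.04). Leaving out 1 cell moved a summed CPM by over 1.5 times in 2 of these. These and the 12 lowest were picked for their size from the 6260 of 10004 genes with reads in at least 12 cells whose summed CPM and share of cells did not go the other way, so their sizes include chance.

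Genes of transmitter receptors lay on both sides. Of 15 ionotropic glutamate receptor genes, 7 were higher and 8 lower in the Sst line, and their median of -0.02 (percentile 54.6) changed sign with the scaling. Grik5, a kainate receptor subunit, was read in 9 Sst-line and 21 Htr3a-line cells (-1.90, and by summed CPM -0.22, or -1.10 without Sst line replicate 1), while Grin2a (1.04) and Gria4 (0.97) were higher in the Sst line. Of 6 metabotropic receptor genes, 5 were lower (median -0.42, percentile 13.9), with Grm7 at -2.07 and Grm4 at -0.65 (-1.47 by summed CPM). Of 11 GABA receptor genes, 9 were higher (median 0.11, percentile 83.7), with Gabrb2 at 1.03, while Gabrb1 (-1.73, and by summed CPM -0.57, or -1.36 without Sst line replicate 21) and Gabra4 (-1.12) were lower. Of 6 acetylcholine receptor genes, 5 were lower (median -0.75, percentile 7.71), with Chrna4 at -1.17 (-2.38 by summed CPM, from -3.44 to -1.86 with each cell left out), Chrm3 at -0.96 and Chrnb3 at 1.30.

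Ion channel lists lay inside the middle 95% of random lists. Sodium channel genes had a median of 0.11 (percentile 79.6) that changed sign with the scaling, with Scn3a at -0.87 and Scn2a1 at -0.73. Potassium channel genes had a median of -0.27 (percentile 47.5), 9 higher and 12 lower, with Kcnb2 at -1.32 (by summed CPM -0.25, or -1.28 without Sst line replicate 17) and Kcna6 at -1.30. Calcium channel genes had a median of -0.19 (percentile 59.1), with Cacnb4 at 1.67 and Cacna1a at 1.03. Cacna1b was at -0.96 but higher in the Sst line by summed CPM (44.9 against 32.7). Channel genes of the HCN family, which carry the hyperpolarization-activated current, had a median of -0.58 (percentile 30.8), with Hcn2 at -0.58. Hcn3 was at -0.76 but higher in the Sst line by summed CPM (88.8 against 55.6).

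Of 16 synaptic vesicle release genes, 14 were higher in the Sst line (median 0.31, percentile 92.9), with Rims1 at 1.02 and Unc13a at 0.82, while Rims2 was at -1.17. Neurexins and their partners had a median of -0.12 (percentile 67.4), 7 higher and 7 lower. Cbln4 was at 1.07 (by summed CPM 0.87, or -0.009 without Sst line replicate 9). Nrxn2 was at -0.81 (by summed CPM -0.09, from -0.67 to 0.11 with each cell left out). Lrrtm4 was at -0.94, with a summed CPM of 18.9 in the Sst line, 7.32 without Sst line replicate 1, and 16.1 in the Htr3a line. Neuropeptide genes had a median of -0.37 (percentile 16.8), with Sst and Pnoc as above and Cort at 0.34. The summed CPM of Cort was 18.4 in the Sst line and 3.75 in the Htr3a line, a log2 ratio of 2.03 (1.58 to 2.27 with each cell left out). Of 11 immediate early genes, which report recent activity, 8 were lower (median -0.26, percentile 20.8), with Nr4a1 at -1.18 and Egr1 at -0.69. Ier2 was at -1.08, with a summed CPM of 89.9 in the Sst line, 65.8 without Sst line replicate 7 and 70.5 without replicate 2, and 76.3 in the Htr3a line. Of 11 heat shock and stress genes, 7 were higher (median 0.26, percentile 85.5), with Hspa5 at 1.01 (0.33 by summed CPM), Gadd45b at -1.97 and Dnajb1 at -0.91.

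Of 13 mitochondrially encoded genes, 11 were lower in the Sst line (median -0.47, percentile 1.5), led by mt-Co3 (-1.14), mt-Co2 (-1.01) and mt-Atp6 (-0.98). The counts of these 3 are uncertain, since 99.9%, 100% and 99.5% of their 31-base words also occur in other annotated genes. The percentile was 6.54 on the deposited normalized scale, and up to 4.32 when 1 cell was left out (Sst line replicate 13).

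**Figure D4:**
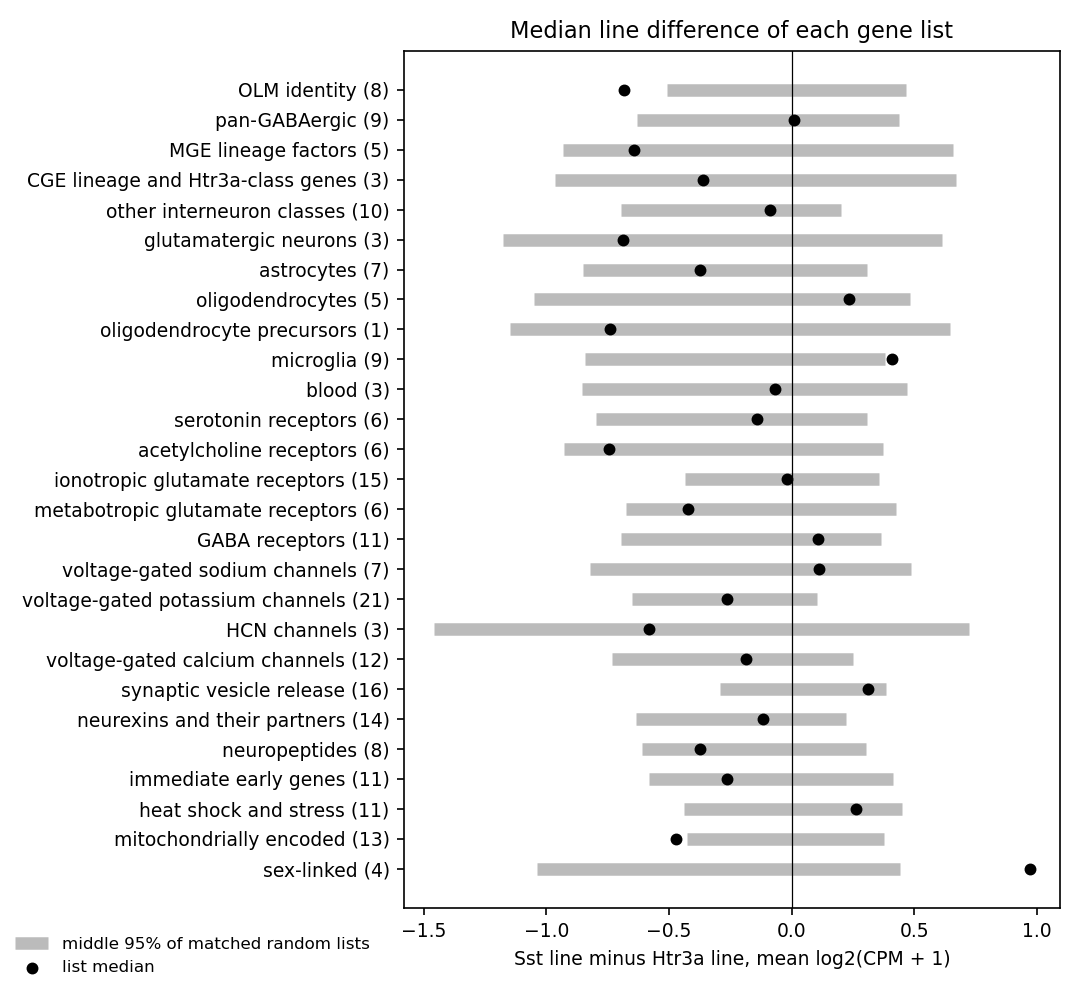
Median line difference in mean log2(CPM + 1), Sst line minus Htr3a line (horizontal axis), of each gene list (vertical axis, members used in brackets), with grey bars for the middle 95% of 10000 matched random lists. The OLM identity (-0.69) and mitochondrial (-0.47) medians lie below their bars and the microglia (0.41) and sex-linked (0.97) medians above, while the pan-GABAergic, blood, ionotropic glutamate receptor and sodium channel medians change sign with the scaling.

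Mean profiles of 11 cells from each line correlated across 11196 genes with a median r of 0.890 (range 0.873 to 0.902 over 100 draws). Disjoint sets of 11 cells within a line correlated with a median r of 0.896 (0.874 to 0.907) in the Htr3a line and 0.889 (0.875 to 0.899) in the Sst line. The ranges overlap. The correlation is across genes, which are not independent replicates, and does not exclude differences in single genes.

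Transcripts of other cell types were read in cells of both lines. The 9 microglial genes summed to a median of 448 CPM in Htr3a-line cells (range 0 to 8443) and 774 CPM in Sst-line cells (0.0536 to 10876), and reached 100 CPM in 16 and 18 cells. Of these, 8 were higher in the Sst line, led by C1qa (1.15, and by summed CPM 0.09, from -0.19 to 0.42 with each cell left out), C1qc (0.80) and P2ry12 (0.67), with a list median of 0.41 (percentile 98.1). That percentile was 94.9 after thinning and ranged from 89.1 to 99.8 with each cell left out, lowest without Htr3a line replicate 1. Oligodendrocyte genes summed to medians of 158 CPM in the Htr3a line and 282 CPM in the Sst line. Their means over cells went the other way, at 1128 and 822 CPM. Mobp was at -0.38 and Cnp at 0.37, or 0.62 by summed CPM (list median 0.23, percentile 91.8). Astrocyte genes summed to medians of 89.3 and 143 CPM, but to means of 245 and 233 CPM. Glul was at -0.38, S100b at -0.37 and Slc1a2 at -0.31 (list median -0.37, percentile 34.3). By summed CPM, S100b was at -0.68 (-1.40 to -0.34 with each cell left out) and Slc1a2 at -0.75 (-1.54 to 1.12).

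Glutamatergic genes summed to medians of 46.4 CPM in the Htr3a line and 24.8 CPM in the Sst line, with Camk2a at 1.15, Fibcd1 at -1.05 and Nrgn at -0.69. Their list median of -0.69 (percentile 18.3) was 1.15 with a minimum mean of 2. Slc17a7, the vesicular glutamate transporter of pyramidal cells, was chosen after its values were seen and was read in 2 Htr3a-line and 0 Sst-line cells. Genes of other interneuron classes summed to 385 and 367 CPM, with Ndnf at -1.41 (-0.37 by summed CPM), Pvalb at 1.29 and Cnr1 at 0.10, of either sign by scaling (list median -0.09, percentile 76.3). Oligodendrocyte precursor, vascular and blood genes had medians of 0 CPM in both lines. Of the precursor genes, 1 was above the expression minimum (Olig1, chosen after its values were seen, -0.74, percentile 9.48). Blood genes had a list median of -0.07 (percentile 65.3) that changed sign with the scaling, and of the vascular genes 0 were above the minimum and 1 had reads in at least 12 cells (Pecam1, 0.24, and by summed CPM 0.84, from -0.46 to 1.51 with each cell left out).

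Y-linked genes were read in more Sst-line cells. Eif2s3y had reads in 15 Sst-line and 10 Htr3a-line cells (1.67), Ddx3y in 14 and 6 (1.42) and Kdm5d in 7 and 5 (0.52). By summed CPM, Ddx3y was at 2.15 (1.39 to 2.64 with each cell left out) and Kdm5d at 1.89 (1.0 to 3.38). Uty, chosen after its values were seen, was read in 8 Sst-line and 6 Htr3a-line cells (0.16). Its summed CPM was slightly lower in the Sst line, at 23.6 against 24.8. The median of the 4 sex-linked genes analysed, all Y-linked, was 0.97 (percentile 99.95). The labels used here give no sex of the animals.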

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

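No paired analysis was possible because replicate numbers were given in accession order and the results come from no test. Of 1044 alternative values of line differences, 830 lay within 0.58 of the main value and 207 moved further. Another 7, of genes with a main size of at least 0.5, took the other sign, each as the log2 ratio of summed CPM with 1 added, which lets cells with many reads set the value: Pnoc 0.59, Lhx6 0.042, Sox6 0.56, Hcn3 0.67, Cacna1b 0.45, Lrrtm4 0.22 and Ier2 0.23. In an alternative chosen after seeing the data, each cell left out of the sums, the sign changed for Pnoc (-0.15 to 0.94), Lhx6 (-0.31 to 0.14), Lrrtm4 (-1.04 to 0.48) and Ier2 (-0.21 to 0.46). Among other genes with a summed log2 ratio of at least 0.5 in size, it changed for Htr3a (-3.58 to 0.74), Adarb2 (-4.13 to 1.51), Slc1a2 (-1.54 to 1.12), Pecam1 (-0.46 to 1.51), Npy (-0.13 to 0.87), Dlx6 (-0.11 to 1.21) and Cbln4 (-0.009 to 1.51). Genes with smaller ratios, such as Mobp, Htr1a and Htr2a, changed sign too. Of 116 genes, a pseudocount of 10 moved 43 by over 0.58, the deposited scale 52, summed CPM 46 besides those 7 and medians 66, while TMMwsp, poscounts, thinning and leaving out 1 cell moved 0. The Sst difference lay between -1.55 and -1.02 in these. The percentile of the OLM list was 3.69 with a pseudocount of 10, 2.92 after thinning, and from 0.05 to 3.49 with each cell left out (the cause was not tested). The glutamatergic median was 1.15 with a minimum mean of 2, which leaves fewer genes. With a minimum mean of 3 the profile correlations were 0.817 between the lines, 0.821 within the Htr3a line and 0.814 within the Sst line, over fewer genes. The numbers of genes per cell moved by less than 1.5 times in 6 of 6 values, and 359 of 384 shares of cells stayed inside the main intervals. These intervals are wide at 23 cells, and most alternatives could hardly leave them. With 10 CPM as the detection minimum, 15 of 64 shares moved outside. Of 16 medians of CPM summed over a list of another cell type, 13 moved by over 1.5 times or from 0 when taken as means over cells. A gene with reads in 0 of 23 cells may have reads in up to 13% of such cells.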

Other observations

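The 2 tests on microglial transcripts were set before their results were seen, and the tests on Htr3b, on Sst and on shared sequence were chosen after. Immediate early genes were read in both lines: Fos and Dusp1 in 23 of 23 cells of each, Junb in 22 of each, Arc in 12 Sst-line and 13 Htr3a-line cells and Npas4 in 8 and 9. Of the other serotonin receptor genes, Htr7 was read in 5 Sst-line and 4 Htr3a-line cells, Htr1b and Htr1d in 0 and 3 each, and Htr4 in 0 and 2. These genes were chosen after their values were seen.

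Eno1b, most of whose sequence (89.2% of 31-base words) occurs in other genes, had a line difference of -1.67, and Eno1 had 0.75. After these were seen, 4 sets of genes were split into 5 strata by the share of such words. Genes with at least 50% against those under 5% had medians of -0.18 (42 genes) and 0.21 (230) among genes read in every cell, -0.13 (162) and 0.09 (1141) among genes read in 40 cells or more, 0.04 (62) and 0.14 (769) at a mean above 6, and -0.24 (522) and -0.23 (7043) at a mean of at least 0.5. The gap was widest in the first set and absent in the last.

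Htr3b was read in 11 Htr3a-line cells and 0 Sst-line cells, and was picked from many genes. Lower gene detection in Sst-line cells is argued against by 932 genes matched to Htr3b on cells with reads (9 to 13) and level in the Htr3a line, a match set after another had been looked at: 0 had no Sst-line read, which allows up to 0.322%, while among 2520 genes matched on cells alone 1 had none (Zfp141). RNA of neighbouring interneurons that express Vip or Cck is argued against, since these genes summed to 0.152 times the CPM of Htr3b in the Htr3a line (0.0466 without replicate 10), although Cck was higher there (8.64 CPM, or 2.84 without replicate 10, against 1.75, or 0.740 without Sst line replicate 22 and 1.04 without replicate 14). Such RNA from interneurons that express Ndnf or Nr2f2 cannot be told apart from a difference between the OLM cells, since both genes were higher in the Htr3a line (-1.41 and -1.24, with summed CPM of 105 and 65.4) and summed to 2.96 times Htr3b there (2.52 to 3.68 with each cell left out), but the Sst line held 81.0 and 17.3 CPM of them, in 11 cells each, beside 0 reads of Htr3b, and Lamp5, which many such interneurons express, was read in 0 Htr3a-line cells, and both go against this source without excluding it. An effect on the chromosome around Htr3a, such as a driver transgene could bring, cannot be told apart either, as the 3 genes within 200 kb with enough reads had a median of -1.11 (Usp28 -1.50, Zbtb16 -1.11, Zw10 0.50) but summed CPM of 24.4, 15.5 and 13.2 in the Htr3a line against 17.3, 11.1 (7.0 without Sst line replicate 22) and 42.8, and the animals and their sex stay open as untested.

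Sst was lower in the line driven by Sst. Scaling is argued against, since the difference closest to 0 over 3 scalings and thinning was -1.31. A shift of abundant transcripts is argued against by the other 159 genes with a mean above 9, whose median was 0.29 (with Sst included, 0.14 after thinning) and of which 0 lay below Sst. A lower level of most OLM genes cannot be told apart. The other 7 had a median of -0.52, with 3 below -0.58 and 1 above 0.58 (Crhbp, 1.33). A lower level was not shared by all, as Crhbp was higher on each scale (1.07 to 1.39) and by summed CPM (0.39). By summed CPM, Pnoc (0.59), Npy (0.54) and Reln (0.02) were higher too, but each could change sign when 1 cell was left out. The others, such as Elfn1 (-0.97) and Chrna2 (-0.47), were lower by summed CPM. The driver allele, the animals and their sex stay open as untested, and each may lower Sst.

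Microglial transcripts differed widely between cells of both lines. The SD over cells of the list's mean log2(CPM + 1) was 2.99 (3.10 within the Htr3a line and 2.92 within the Sst line), against a median of 1.21 and a highest value of 1.67 over 10000 matched random lists. The random lists were matched on mean expression and not on how genes vary together. Genes that vary together would exceed them whatever the cause. The comparison therefore cannot decide whether microglial RNA was taken up with some cells, as a pipette that crosses tissue could do. Reads crossing between libraries cannot be told apart from such uptake, because 21 genes reached 1500 CPM in a cell with no read in 23 cells or more, but the highest cells of these genes lay in 7 libraries. Microglial C1qb reached 3015 CPM in an Htr3a-line cell and 2106 in an Sst-line cell, and no biological explanation was tested.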
